A study of Homo sapiens with 6 samples.

How the data were processed

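Total RNA of HEK293 cells, a human embryonic kidney cell line, was measured on 6 Illumina expression beadchips, 3 of uninfected control cells and 3 of cells infected with a lentiviral vector that carries CEBPA, a transcription factor of myeloid, liver and fat cells. Per the labels' protocols, the RNA was amplified and labelled with biotin before hybridization. One sentence of the labels' extraction protocol names monocytes as the source, whereas the sample labels name HEK293. The control cells were uninfected, and no array of cells infected with an empty vector was analysed here. No label says whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

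The authors deposited a table of bead intensity values for 47322 probes per array, together with a detection p-value per probe and array. The submitters' processing notes name BeadStudio and R 2.15.2. Judged from the values, the deposited intensity values were neither background-subtracted nor normalized between arrays, since their medians differ and lie close to the background. By Illumina's convention, the detection p-value of a probe is the share of negative control probes that were brighter. The deposited series table holds log2 values of the same arrays. Its direction and scale were checked against the intensities. The sorted log2 values differed from the log2 of the mean sorted intensities by at most 0.000242, so they are quantile-normalized intensities without background correction and without centring. Their median was 6.79 on every array. No pair of intensity columns was identical.

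For the main results, the background was corrected by the normexp model with negative control values inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalized and put on the log2 scale (function neqc of limma 3.58.1 in R 4.3.3). Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 20896 probes. Gene names came from the platform's annotation table. Of the probes on the array, 30112 had 1 gene symbol, 8 had several and 17202 were not listed there; for 30073 of them the gene ID was found among the RefSeq genes of GRCh38.p14, and no symbol needed an update. Each gene was represented by its probe with the highest mean over all 6 arrays, which gave 12070 genes. Probe positions and sequences were not used here, so no coordinates are given, and probes of near-identical genes (ORM1 and ORM2, the AKR1C genes, HSPA1A and its copy, histone and metallothionein genes) may read each other's RNA.

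The groups were compared with limma (lmFit and eBayes, 2-sided), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Adjusted p-values in the text come from this fit unless another is named. A log2 difference is given with its moderated standard error (SE) and is CEBPA vector minus control. "Rose" and "fell" refer to genes with an adjusted p under 0.05. Where no probe of a gene was detected on any array of a group, the change is given as a lower bound, "at least N-fold": the mean of the brighter group against the dim group's mean of, per array, the higher of the gene's own value and the lowest value among detected probes. The number of arrays limits the precision.

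Before the data were examined, 29 gene lists were fixed for cell types and pathways that fit the vector and the cells, as were the tests and the alternatives. The 26 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. CEBPA was in no list. The genes named are CEBPA, the 12 with the largest increase and the 12 with the largest decrease among those past the test whose groups did not overlap, and from each list up to 4 members past the test with the largest change, or 2 where none passed. Genes without a symbol of their own were counted but were not among the 12. Genes outside this rule are marked as chosen after their values were seen.

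The fit was tested on simulated arrays of the same comparison, with a background like that of these arrays, of which 20358 probes were tested. It recovered 47.8% of 67 probes changed 1.5-fold, 77.3% of 66 changed 2-fold and 89.4% of 66 changed 4-fold, and 13 of 155 calls were false (8.39%). These rates describe the simulated arrays only. The simulated noise had a log2 SD of 0.077. Named genes of the real arrays lay on both sides of it, with SDs of 0.0059 for CD1D and 0.38 for GPM6A in the infected cells. Few simulated probes were changed, whereas 31.5% of the real genes changed. Recovery at a larger spread or share of changed genes was not tested. The list test called the list of changed probes and none of 20 random lists. The changed list held only probes given an increase, so its call was fixed. Simulated noise was independent between probes, so the random lists do not test the preset correlation.

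Slides were not named in the files, so the planned slide block was not run. Other alternatives were other background corrections and normalizations, other filters on dim probes, the authors' log2 values, another variance model, the mean of a gene's probes, array weights, a replicate block, other list tests, a test against a fold of 1.2 and leaving out each array in turn.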

Results

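Gene expression was compared between HEK293 cells infected with the CEBPA vector (3 arrays) and uninfected HEK293 cells (3 arrays). The design addresses which genes differ after infection with the CEBPA vector, in a cell line that is not of the myeloid lineage. Between 20176 and 21606 of the 47322 probes were detected per array, and the median bead intensity lay between 103.4 and 117.2, close to the background of 86.9 to 97.8. Arrays of one group correlated at 0.992 or more over the kept probes, and arrays of different groups at 0.974 or less. The first principal component separated the groups and held 73.0% of the variance. The second, with 8.81%, set CEBPA replicate 3 apart from CEBPA replicates 1 and 2.

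The only probe annotated to CEBPA here, ILMN_1715715, did not pass the test. It was detected on all 6 arrays, at a normalized log2 intensity of 9.93 ± 0.11 (SD, n = 3) in the control cells and 10.13 ± 0.06 (SD, n = 3) in the infected cells. The log2 difference was 0.20 (SE 0.08, limma adjusted p = 0.098). The 3 infected arrays lay above the 3 control arrays, with the lowest infected value at 10.06 and the highest control value at 10.05. With a robust variance model that follows intensity the adjusted p was 0.034, and over all alternatives it ranged from 0.034 to 0.24. The part of the transcript that the probe reads, and the part carried by the vector, are not given in the sources used here. A probe outside the insert would not read the vector's RNA, so this probe does not settle whether the vector was expressed. Of the other members of the CEBP family, CEBPB rose by 0.43 (SE 0.08, adjusted p = 0.0060) and DDIT3, a stress-induced family member, by 0.45 (SE 0.08, adjusted p = 0.0054). The other 3 measured members, of 5, did not pass, and the list as a whole was not called (camera adjusted p = 0.51).

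Of 12070 genes, 3798 changed (31.5%), of which 1715 rose and 2083 fell. This balance depended on the scaling between arrays: 45.2% of the changed genes rose here, 53.5% without normalization between arrays and 50.4% with cyclic loess. The groups did not overlap for 47.8% of all genes, against 10% by chance. A change of at least 2-fold was seen in 327 genes that rose and 254 that fell, and one of at least 8-fold in 44 that rose and 4 that fell. With genes not detected in a group set to their bound, an alternative chosen after seeing the data, these numbers were 299 and 233, and 38 and 3. In 132 of the genes that rose no probe was detected on any control array, and in 93 of those that fell none was detected on any infected array. Without background correction, as in the authors' log2 values, 190 genes rose and 111 fell by at least 2-fold, and 19 rose and 1 fell by at least 8-fold.

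The largest increases were in S100A8 and S100A9, calcium-binding proteins of neutrophils and monocytes. Neither was detected in the control cells; in the infected cells they had a log2 intensity of 13.70 ± 0.05 for S100A8 and 13.69 ± 0.09 for S100A9 (SD, n = 3). S100A9 was at least 288-fold higher (adjusted p = 1.04e-07) and S100A8 at least 292-fold higher (adjusted p = 1.10e-08). The secreted protease inhibitors SLPI and PI3 were at least 132-fold and 89.5-fold higher. Haptoglobin (HP), a plasma protein of the acute phase, was at least 58.6-fold higher, and the acute phase protein gene ORM1 at least 27.2-fold. CSF3R, the receptor for granulocyte colony-stimulating factor, was at least 33.3-fold higher. The carboxylesterase CES1 was at least 31.7-fold higher and the receptor for oxidized low-density lipoprotein OLR1 at least 29.5-fold. A second CES1 probe, also detected on no control array, was at least 1.21-fold higher. Genes already detected in the control cells followed. CGA, the alpha subunit of the glycoprotein hormones, rose 31.0-fold. PTGS2, the inducible prostaglandin synthase, rose 25.7-fold, and CD1D, which presents lipid antigens, rose 25.4-fold. The adjusted p of these 12 genes was at most 3.70e-07 (CGA). Without background correction, in the authors' values, the log2 differences of these last 3 genes were smaller: 4.61 for CGA, 4.14 for PTGS2 and 3.99 for CD1D, against 4.95, 4.69 and 4.67. The bounds depend on that correction too. By the same rule in the authors' values, an alternative chosen after seeing the data, they were at least 113-fold for S100A8, 112-fold for S100A9, 51.5-fold for SLPI, 35.1-fold for PI3, 23.3-fold for HP, 13.5-fold for CSF3R, 12.8-fold for CES1, 12-fold for OLR1 and 11.1-fold for ORM1.

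**Figure D1:**
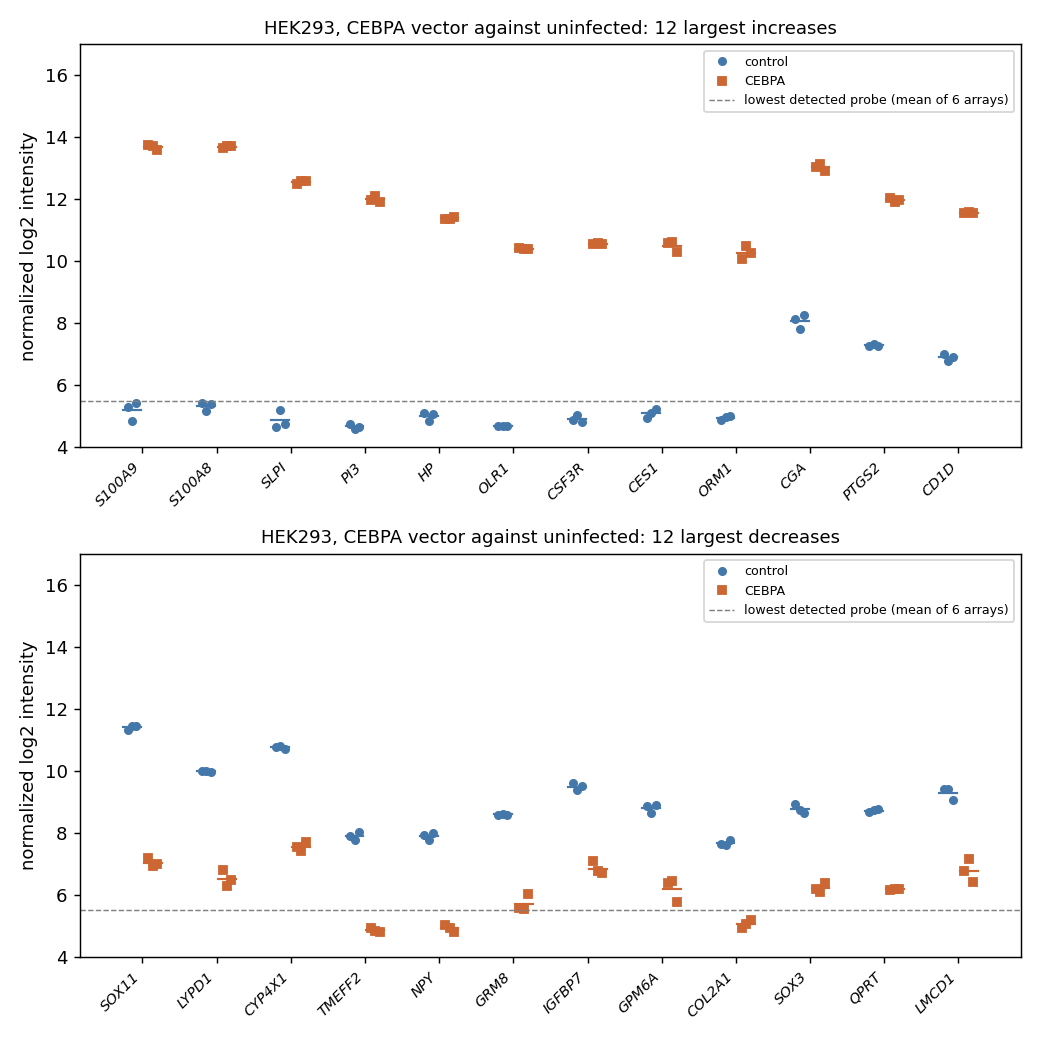
Normalized log2 intensity per array for the 12 genes with the largest increase (top) and the 12 with the largest decrease (bottom). Circles are control arrays, squares are CEBPA vector arrays, short lines are group means (n = 3) and the dashed line is the lowest value of a detected probe, averaged over the 6 arrays; S100A8 and S100A9 lie below that line in the control cells and near 13.7 in the infected cells.

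The largest decreases were led by SOX11, a transcription factor of neural progenitors, which fell 20.6-fold from a log2 intensity of 11.41 ± 0.06 to 7.04 ± 0.14 (SD, n = 3; adjusted p = 1.61e-07). SOX3, another member of the SOX family, fell 5.91-fold. LYPD1 fell 11.1-fold, with a log2 difference of -3.47 on this probe and -1.31 on another (detected on 2 of the 3 infected arrays), and the cytochrome P450 gene CYP4X1 fell 9.23-fold. Neuropeptide Y (NPY) and TMEFF2 were no longer detected in the infected cells and were at least 5.27-fold and 5.28-fold lower. The type II collagen gene COL2A1 was at least 4.52-fold lower. The glutamate receptor GRM8 fell 7.38-fold, IGFBP7 6.25-fold, the neuronal membrane protein GPM6A 6.15-fold, QPRT 5.82-fold and LMCD1 5.72-fold. The adjusted p of these 12 genes was at most 7.49e-05 (LMCD1). In the authors' values the log2 difference of SOX11 was -3.75 against -4.37 and that of GRM8 -1.87 against -2.88, and the bounds were at least 2.67-fold for NPY and TMEFF2 and 2.38-fold for COL2A1.

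Of 16 measured myeloid transcription factors, 9 rose and none fell (9 and 2 when adjusted over the list alone). The other 7, GFI1, IRF4, TFEC and MAF among them, were not called, and SPI1, JUNB and NR4A1 were not measured above background. IRF8, a regulator of monocyte development, rose 7.94-fold, FOS 3.53-fold and KLF2 2.38-fold, and BCL6 rose by 1.59 on the log2 scale. As a set these factors were called as higher (median log2 difference 0.36, camera adjusted p = 0.0038), and not with an estimated correlation (adjusted p = 0.22). Of 30 monocyte and macrophage surface markers and receptors, 9 were measured above background; 4 rose and none fell (5 and none over the list alone). Without the filter on dim probes 4 of 29 rose, with a median of 0.086 against 0.34. The measured markers that rose beside CSF3R were CD14, the lipopolysaccharide co-receptor, with a log2 difference of 0.46 (SE 0.07), CD68 with 0.64 (SE 0.14) and the integrin ITGB2 with 0.45 (SE 0.08). Other probes of CD68 and ITGB2 disagreed: CD68 probes ranged from -0.09 to 2.08 and a second ITGB2 probe gave -0.04, and the call of ITGB2 was lost with the mean of its probes. These markers were called as higher (camera adjusted p = 0.029), not without CEBPA replicate 1 (adjusted p = 0.053; range over the alternatives 0.022 to 0.053), and not with an estimated correlation (adjusted p = 0.22). Of 18 granule genes of granulocytes, 17 had a probe in the annotation used here and only 4 were measured above background, too few for a list test. All 4 rose, whereas without the filter on dim probes 6 of 17 rose and none fell, with a median of 0.12, and the list was called as higher (camera adjusted p = 0.00086). Not detected on any control array, MMP8 was at least 3.70-fold and RNASE2 at least 3.26-fold higher (at least 2.07-fold and 1.90-fold in the authors' values). LCN2, detected on 1 of the 3 control arrays, rose 4.56-fold (4.10-fold with control values under the detection floor set to it) and CHI3L1 3.65-fold. With a detection p under 0.01 required on all 6 arrays none of the 4 was tested. In the list of transcripts abundant in blood monocytes, 4 of 12 rose and 2 fell. SRGN was at least 3.49-fold higher (at least 1.99-fold in the authors' values) beside S100A8 and S100A9, whereas the class II gene HLA-DPA1 fell 2.30-fold. The median of this list was -0.03 and its mean 1.43, and it was not called (camera adjusted p = 0.29).

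Of 28 cytokines, chemokines and related genes, 7 were measured above background; 4 rose and 1 fell (6 and 1 over the list alone). The median was 0.80, or 0.34 with genes not detected in a group at their bounds; without the filter on dim probes 6 of 27 rose and 1 fell, with a median of 0.13. Beside PTGS2, the chemokine CCL20 was at least 1.75-fold higher and CXCL8 rose 1.89-fold (log2 difference 0.92, and 1.99 on another probe), while CCL2, a monocyte chemoattractant, was at least 1.67-fold lower. Together they were called as higher (camera adjusted p = 0.0080; adjusted p = 0.22 with an estimated correlation). Of 22 acute phase and complement genes, 8 were measured above background; 4 rose and 2 fell, both over all genes and over the list alone. The 4 that rose (HP, ORM1, ORM2 and FGA) were not detected on any control array, and none was tested with the stricter detection filter. The median was 0.65, or 0.45 with these 4 at their bounds; without the filter on dim probes 5 of 21 rose and 1 fell, with a median of 0.023. ORM2 was at least 16.3-fold and the fibrinogen gene FGA at least 1.66-fold higher (at least 6.91-fold and 1.28-fold in the authors' values). The 2 decreases each lost their call in at least 3 of the 6 fits that left out 1 array, and both did without control replicate 1, CEBPA replicate 1 or CEBPA replicate 3. Acute phase and complement genes were called as higher (camera adjusted p = 0.017; adjusted p = 0.22 with an estimated correlation). Among 16 measured NF-kB targets, 7 rose and 1 fell, also over the list alone: NFKBIZ, a nuclear regulator of inflammatory genes, rose 2.38-fold, CFLAR 1.74-fold and SOD2 1.53-fold, and PLAU, detected on 2 of the 3 infected arrays, fell 1.83-fold. This list was at the threshold (camera adjusted p = 0.049). Its call was lost without control replicates 1, 2 or 3 or CEBPA replicate 1 (adjusted p = 0.055, 0.053, 0.073 and 0.086), without normalization, with cyclic loess or with the replicate block (adjusted p = 0.075, 0.056 and 0.072), and with an estimated correlation (adjusted p = 0.23).

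Interferon-stimulated genes moved in both directions, with more increases. Of 29 measured, 13 rose and 3 fell (17 and 3 over the list alone). OAS3, an antiviral enzyme, rose 3.56-fold and the nuclease ISG20 3.28-fold, whereas IFITM1 was at least 1.48-fold lower. PSMB9 was at least 2.04-fold higher on one probe, which was not detected on any control array, and gave -0.01 (SE 0.21) on the other. Which of them was brighter changed with the setting, and PSMB9 gave 0.018, 0.021 and -0.067 without CEBPA replicates 1, 2 and 3 and was not called there. Nor was it called with normexp without negative controls (0.019), without background correction or in the authors' values (0.017 in both). As a set the interferon-stimulated genes were called as higher (median 0.25, camera adjusted p = 0.0080, and 0.22 with an estimated correlation).

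Of 19 measured targets of p53, 12 fell and 1 rose (13 and 2 over the list alone). CDKN1A, the cyclin-dependent kinase inhibitor p21, fell 2.49-fold (log2 difference -1.32, SE 0.08, adjusted p = 3.71e-05), GADD45A fell 1.66-fold and the apoptosis gene BAX 1.71-fold, though a second BAX probe did not pass. TP53I3 rose 1.79-fold. The p53 targets were called as lower (median -0.41, camera adjusted p = 0.0080; adjusted p = 0.24 with an estimated correlation). Among 7 measured CDK inhibitors, CDKN1A fell and CDKN2D rose 1.53-fold, and the list was not called (camera adjusted p = 0.96). Of 24 DNA replication genes, 7 fell, TYMS by 1.53-fold and POLA1 by 1.46-fold among them, and 1 rose (7 and 1 over the list alone); 4 fell without CEBPA replicate 2, and 3 without normalization between arrays. That list was not called (camera adjusted p = 0.065), but was without the filter on dim probes (adjusted p = 0.025) and with the mean of probes (adjusted p = 0.043). Of 26 mitotic genes, 3 fell and AURKA, a mitotic kinase, rose 1.63-fold, with a median of -0.03 that turned to 0.00048 with cyclic loess normalization (camera adjusted p = 0.96). With cyclic loess or the robust variance trend 4 mitotic genes rose and with the authors' values 3, and without normalization between arrays 1 fell. In the CDK inhibitor list the median was -0.06 while camera's direction was up.

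Of 13 measured histone genes, 8 fell and none rose (9 and none over the list alone), led by H2AC18 (1.96-fold, though a second probe gave -0.50 with adjusted p = 0.074), H2BC21 (1.62-fold) and H2AC20 (1.51-fold); 5 fell without control replicate 3 or without CEBPA replicate 1. Histone genes were called as lower (median -0.34, camera adjusted p = 0.0080; adjusted p = 0.22 with an estimated correlation). Of 31 chromatin remodelers and histone modifiers, 9 fell and 3 rose (12 and 3 over the list alone); 4 fell without normalization between arrays, 12 with median scaling and 14 with the robust variance trend. HDAC1, a histone deacetylase, fell 1.38-fold, SMARCB1, a subunit of the SWI/SNF remodeler, fell 1.30-fold and KMT2A fell 1.32-fold, while EED, a Polycomb protein, rose 1.37-fold. These genes were called as lower (median -0.16, camera adjusted p = 0.038; adjusted p = 0.23 with an estimated correlation). The call was lost without control replicates 1 or 3 or CEBPA replicate 1 (adjusted p = 0.055, 0.052 and 0.086) and without normalization (adjusted p = 0.075), and 5 members fell without control replicates 2 or 3 or CEBPA replicates 1 or 3.

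The remaining lists were not called by camera with the main settings. Among 12 adipocyte genes measured above background, of 21 listed, 4 rose and none fell. LPL, lipoprotein lipase, rose 3.02-fold, PPARG, the regulator of fat cell formation, 1.99-fold, PLIN2 1.95-fold and ADIPOR2 1.33-fold (adjusted p = 0.13 for the list). FABP4, ADIPOQ and PLIN1 were among those not measured above background, and without the filter on dim probes 4 of 20 rose and none fell. Of 11 hepatocyte genes 4 rose, among them RBP4, detected on 1 of the 3 control arrays, 6.03-fold (5.35-fold with control values set to the floor) and albumin (ALB) 2.41-fold, and 4 fell, among them ASGR1 1.65-fold; their median was -0.06 and their mean 0.28 (adjusted p = 0.63). Of 14 neural and kidney genes associated with HEK293, 7 fell and 1 rose; ENO2 fell 2.67-fold, NEFL 2.17-fold and LHX1 was at least 2.01-fold lower (adjusted p = 0.067 for the list, 0.025 without the filter on dim probes and 0.039 without normalization). Among 21 targets of ATF4, 11 fell and 3 rose, with DDIT4 falling 2.18-fold and TRIB3 rising 1.97-fold (adjusted p = 0.12). Of 22 hypoxia and glycolysis genes 4 rose, HK2 3.13-fold among them, and 7 fell (adjusted p = 0.67; 6 and 10 over the list alone, and 6 and 11 with the robust variance trend). Of 16 cholesterol synthesis genes 5 rose (3 without CEBPA replicate 1) and 3 fell (adjusted p = 0.34), and of 16 unfolded protein response genes 2 rose, XBP1 by 1.44-fold, and 1 fell (adjusted p = 0.33). Among 13 heat shock genes, 2 rose and 2 fell, HSPB1 by 1.86-fold (adjusted p = 0.96); in each fit that left out 1 array, 1 fell. Their median was -0.02, and 0.014 with cyclic loess or without normalization. MT1F rose 2.69-fold and MT2A fell 1.85-fold among 4 metallothioneins. None of 19 ribosomal protein genes passed in limma (RPL5 gave -0.16 with adjusted p = 0.11), and 1 did with the robust variance trend. Among 13 common reference genes 4 fell, TUBB by 1.32-fold (its second probe did not pass), and 1 rose (adjusted p = 0.34); 2 fell and none rose without control replicates 2 or 3 or CEBPA replicates 1 or 2, and 2 fell without normalization. Of 8 fibroblast markers 4 fell, ACTA2 by 2.10-fold and COL6A1 by 1.83-fold (adjusted p = 0.13). Of 5 lymphocyte markers 1 rose, CD2, at least 1.38-fold higher (adjusted p = 0.85). Of 4 erythroid markers 1 rose (3 over the list alone), HBG2, detected on 1 of the 3 control arrays (adjusted p = 0.0034 for the gene). These counts cover only genes measured above background. Without the filter on dim probes 4 of 25 hepatocyte genes rose and 4 fell, and 5 of 16 fibroblast markers fell and none rose. In that setting 1 of 15 lymphocyte markers and 2 of 12 erythroid markers rose, and none fell.

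**Figure D2:**
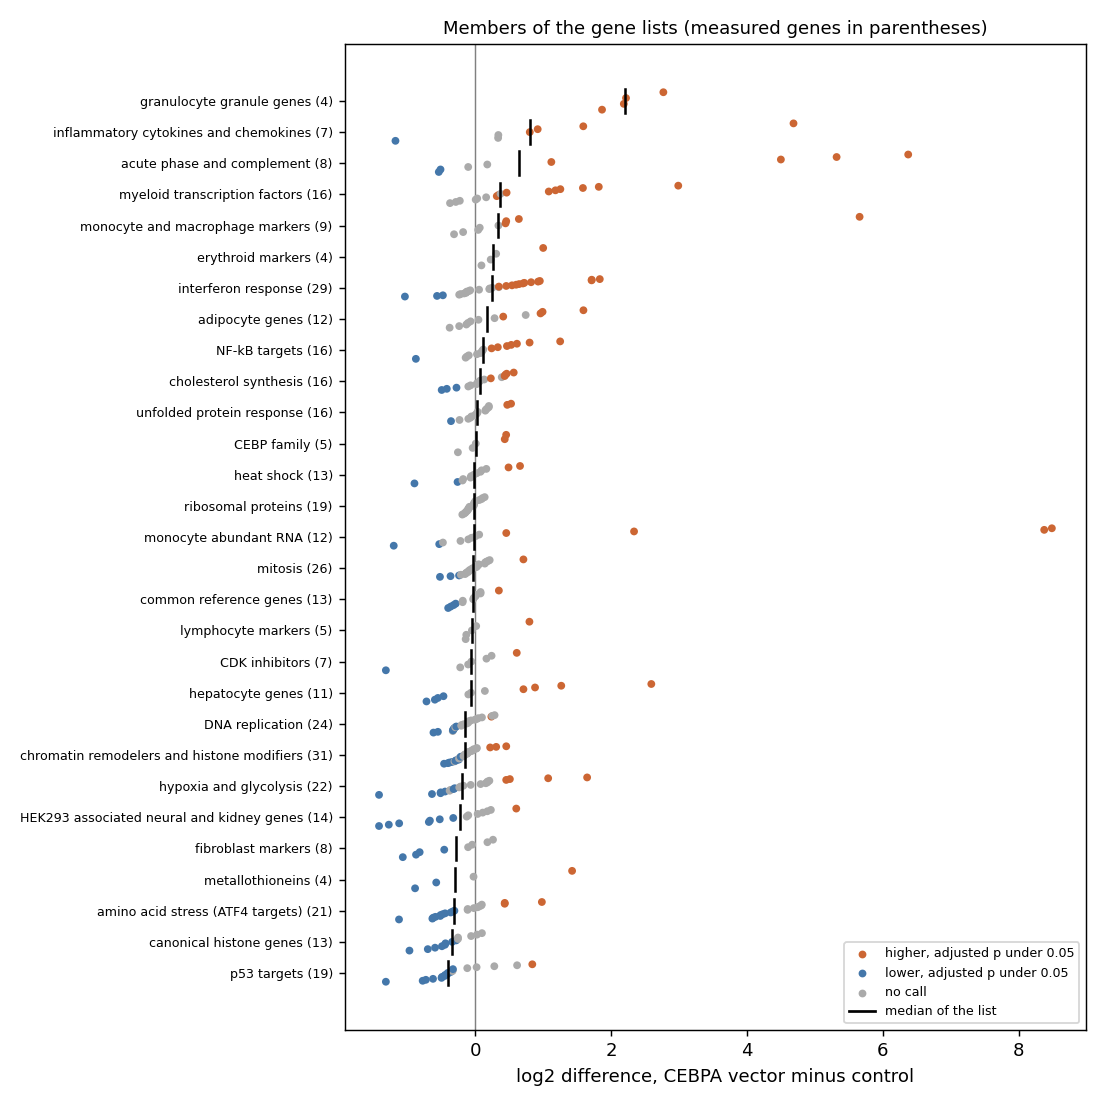
Log2 difference (CEBPA vector minus control) of each measured gene in the 29 lists, ordered by list median, with the number of measured genes in parentheses. Each point is a gene, coloured by its call at an adjusted p under 0.05, and black bars are list medians; the median was -0.41 for p53 targets.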

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

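The comparison of probes without a gene name was not among the tests fixed in advance. Among the probes without a gene symbol in the annotation used here, which no comparison of genes includes, 309 of 4897 were higher in the infected cells and 377 were lower (limma adjusted p under 0.05 over 20896 probes). Together these are 14.0%, against 22.8% of all probes. Neither ILMN_2150856 nor ILMN_2150851 was detected on any control array; they were at least 105.7-fold and at least 98.9-fold higher in the infected cells (adjusted p = 9.32e-08 for both), with log2 intensities of 12.24 and 12.15 there.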

How the results depend on the processing

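The alternatives here were fixed in advance; setting undetected genes to bounds or values to the floor, and bounds in the authors' values, were chosen after seeing the data. Tested against a fold of 1.2, 1378 genes changed; in the other alternatives the number was 2917 to 4513, against 3798. Genes changed at least 2-fold numbered 318 with normexp without negative controls, 301 without background correction and, identically, with the authors' values, and 334 with a detection p under 0.01 on all 6 arrays, against 581. By its construction that filter removes genes not detected in a group, which 9 of the 12 largest increases were; for the others the cause was not tested. No list was called with an estimated correlation, against 9. That estimate exceeded the preset 0.01 for p53 targets (0.092), histone genes (0.034), chromatin genes (0.015) and cytokines (0.012). It was lower for the other called lists, from -0.10 for monocyte markers to 0.0020 for NF-kB targets. A higher correlation does not account for the lost calls of those other lists. Camera called 12 lists without a filter on dim probes and 10 with the mean of probes. DNA replication genes were called in both of these, granulocyte granule genes, untested before, without a filter, and the HEK293 neural and kidney genes without a filter and without normalization. The fry test, which does not compare a list with other genes, called 19 lists. CEBPA passed with a robust variance trend (0.20, adjusted p = 0.034), and the cause was not tested. Over the alternatives other than the test against a fold of 1.2 its adjusted p ranged from 0.034 to 0.24. Leaving out 1 array gave 2917 to 3449 genes changed, 575 to 636 changed at least 2-fold and 6 to 9 lists. Of 118 named genes other than CEBPA, 104 kept direction and side of the threshold wherever tested in 18 alternatives. The test against a fold of 1.2 was not among these 18. PSMB9 gave -0.067 to 1.74 without 1 array, because the brighter of its disagreeing probes changes.

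Medians of lists that were not called crossed 0, and the cause was not tested. Abundant monocyte RNA gave 0.0058 without normalization and 0.0037 without a filter, heat shock genes 0.014 without normalization, 0.014 with cyclic loess and 0.016 with array weights, mitotic genes 0.00048 with cyclic loess, CDK inhibitors 0.054 with the stricter filter and hepatocyte genes 0.026 with array weights. Without 1 array, the ranges were -0.059 to 0.066 for the CEBP family, -0.073 to 0.030 for abundant monocyte RNA, -0.18 to 0.11 for hepatocyte genes, -0.041 to 0.015 for mitotic genes, -0.057 to 0.068 for heat shock genes and -0.14 to 0.026 for lymphocyte markers.

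With the replicate number as a replicate block, 3264 genes changed, 3109 of them shared with the 3798, with 580 genes changed at least 2-fold, and 8 lists were called. The numbers were not taken as pairs: deviations of same-numbered arrays from their group means correlated at -0.0057, 0.018 and -0.00028 over probes. Slides were not named in the files, so no slide block was run. Low signal over background limits genes near background to bounds. In the authors' values these were at least 1.32-fold for CCL20, 1.29-fold for CCL2, 1.21-fold for IFITM1, 1.42-fold for LHX1 and 1.17-fold for CD2.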

Other observations

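The genes of the first paragraph, the 3 added gene lists and the tests on the CEBPA probe were chosen after the main results were seen; TUBB3 of the neural list and IL18 of the inflammasome list had been seen in lists fixed earlier. Among genes picked by eye, AKR1C2 rose 24.3-fold, AKR1C4 16.9-fold and AKR1C3 8.73-fold, the retinaldehyde dehydrogenase ALDH1A1, detected on 2 of the 3 control arrays, rose by 4.08 on the log2 scale, MGST1 8.98-fold, ALDH2 2.81-fold, and GSTA1 was at least 3.01-fold higher (adjusted p at most 1.41e-05, GSTA1). The AKR1C genes are close copies, so their probes may read each other's RNA and may not be independent. The inflammatory caspases CASP1 and CASP4 rose, CASP1 at least 15.3-fold and CASP4, detected on 2 of the 3 control arrays, 20.7-fold. The nicotinic acid receptor HCAR2 was at least 8.12-fold higher, arginase ARG1, detected on 1 of the 3 control arrays, rose 11.8-fold (8.89-fold with control values under the detection floor set to it) and the glycerol channel AQP9 was at least 5.23-fold higher. The chemokine receptor CXCR4 rose 4.24-fold, while its ligand CXCL12 was at least 1.92-fold lower. The long non-coding RNA HOTAIR, detected on 2 of the 3 infected arrays, fell 4.79-fold. In the authors' values the bounds were smaller. They were at least 6.53-fold for CASP1, 3.77-fold for HCAR2, 2.66-fold for AQP9, 1.81-fold for GSTA1 and 1.38-fold for CXCL12.

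Neural genes stood out among the decreases. A list of 29 neuronal and neural progenitor genes, leaving out those seen among the largest decreases, was tested as a hypothesis: of 17 measured, 13 fell and none rose, with a median log2 difference of -0.53 (camera p = 9.62e-06, and p = 0.0089 with an estimated correlation). NCAM1 fell by 1.44, STMN3 by 1.30 and POU3F2 by 1.05 on the log2 scale. Over the alternatives the median lay between -0.64 and -0.38 and the camera p between 1.09e-06 and 2.38e-05. The measured gene TUBB3 is shared with the HEK293 list fixed earlier, which camera called in only 2 alternatives. Of the neuronal genes in that earlier list, ENO2 and NEFL fell, while NEFM, NEFH and INA were not called (log2 differences 0.23, 0.11 and -0.13). None of these was in the added list. The added list was tested on the same arrays that prompted it, so its p-values are not independent support. Without the members of earlier lists, an alternative also chosen after seeing the data, 12 of 16 fell, with a median of -0.51 (camera p = 2.10e-05, and p = 0.010 with an estimated correlation). Lower expression of neural genes may go with the vector, with infection or with a different subline of HEK293, and these were not tested apart.

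Of 18 measured targets of NRF2, a regulator of detoxification genes, 27.8% rose and 1, GCLC, fell (log2 difference -0.33). HMOX1 had the largest increase, 1.48 on the log2 scale. The other 12 were not called, NQO1 (0.046) and TXNRD1 (-0.12) among them. The share that rose lies between the limits set in advance, 50% for an NRF2 response and under 25% against one. Only 3 of 18 rose without control replicate 1, control replicate 3 or CEBPA replicate 3, and 4 without control replicate 2 or CEBPA replicate 2 or with the replicate block; 4 of 20 rose without a filter on dim probes and 4 of 17 with the stricter filter. These lie under the lower limit, while 6 of 18, between the limits, rose with the robust variance trend or the mean of probes. An NRF2 response therefore stays open. The camera p of the list was 0.049, upwards (adjusted p = 0.056 over the 3 added lists). With an estimated correlation the unadjusted camera p was 0.22. Of 8 measured inflammasome genes other than CASP1 and CASP4, 3 rose (CARD16, GSDMD and GSDME) and none fell. CARD16 gave the largest log2 difference, 1.18, and whether its probe also reads CASP1 RNA was not tested. AIM2 and NLRP3 were not called (-0.46 and -0.22). The inflammasome list had a camera adjusted p = 0.056 over the 3 added lists (0.092 without IL18 and the other members of earlier lists). The unadjusted camera p was 0.22 with an estimated correlation, and over the alternatives it lay between 0.019 (without CEBPA replicate 3) and 0.081 (without control replicate 1), with 0.043 in the authors' values. The rule set in advance counted any p above 0.05 against a joint increase, which was ill chosen, since a missed threshold excludes nothing.

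RNA from monocytes in the infected samples is a candidate source of S100A8, S100A9 and CSF3R, since the extraction protocol names monocytes. Transcripts that the control cells also expressed were left out. Of 11 other transcripts abundant in monocytes, only SRGN was detected on all 3 infected arrays, and their median log2 difference was 0.019. S100A8 was at least 292-fold higher (113-fold in the authors' values), which argues against monocyte RNA as the source. Increases within the infected HEK293 cells stay open, as a hypothesis.

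The CEBPA probe may miss the vector's RNA if it lies outside the insert. Its log2 difference of 0.20 cannot decide this, because neither position is given. Swaps of single arrays are argued against by the correlations: the lowest within a group exceeded the highest between groups by 0.018. An exchange of all 6 labels would leave that value as it is.

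The controls were uninfected, so an effect of infection cannot be told apart from one of CEBPA. The median log2 difference of the interferon list, 0.25, with 13 of 29 genes risen, met neither the rule set in advance for a response to infection nor that against one. Such a response could account for part of the interferon genes, and other effects of infection were not tested. Members of the list that went against it, chosen after their values were seen, were IFIT1, which fell (log2 difference -0.56), and ISG15 and IFIT3, which were not called (-0.16 and -0.12).

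With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3798 genes, 581 genes changed at least 2-fold and 9 lists, and was the only 1 of the 10 to give as many. The highest other split gave 0, 0 and 2. Every other split mixes control and infected arrays, so the difference between the groups counts as spread there and hinders calls. The other splits are therefore no measure of the calls to be had without a difference.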
